A study of Homo sapiens with 18 samples.

How the data were processed

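THP-1 RNA was sequenced in 18 poly-A libraries (Illumina Stranded mRNA prep, 500 ng total RNA, AVITI instrument, single reads of 100 bases), 3 libraries for each of the groups 0Ab, 30Ab, 100Ab, 0sAb, 30sAb and 100sAb. The labels give no unit for the dose numbers, and the protocol names a recombinant Aβ42 (rAβ42), a synthetic Aβ42 (sAβ42) and a scrambled peptide. The label sAb resembles the abbreviation of the synthetic one but is not defined in the labels. The labels do not say whether the 3 replicates of a group are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

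The authors deposited 1 table of read counts per gene, and these integer counts are the values used here. Per the file headers the table also holds the GC content of each gene in percent and its length, which were read but not tested. The submitters' processing notes name cutadapt 3.2, Bowtie2 2.4.5, STAR 2.5.2b, SAMtools 1.15.1 and GRCh38. The counting program, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and reads of near-identical copies (CCL4 and CCL4L2, CCL3 and CCL3L3, HSPA1A and HSPA1B, the HLA genes) may be counted in either. Gene positions are those of the deposited table. Of its columns 10 were not used here.

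Counts were scaled by TMM factors (0.777 to 1.231) in edgeR 4.0.16 under R 4.3.3. Genes passed filterByExpr on the group labels with a minimum count of 10 and a minimum total of 15, leaving 16527 of 58233. With 21532578 to 31666625 counts per library 1 CPM before TMM scaling is at least 21.5 reads, and scaling lowers this in libraries with a factor under 1. The median SD of log2 CPM between replicates was 0.13, 0.152 and 0.14 in 0Ab, 30Ab and 100Ab and 0.194, 0.253 and 0.256 in 0sAb, 30sAb and 100sAb. Replicates of a group were told apart from copies of 1 another by the spread of their counts (chi-square per degree of freedom 6.98 to 195.55 over pairs).

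edgeR's quasi-likelihood F test was fitted to all 18 libraries with 1 mean per group (12 residual degrees of freedom), and adjusted p is Benjamini-Hochberg's at a threshold of 0.05. Each gene's spread was thus estimated over both batches, so standard errors inside the Ab batch also carry the spread of the sAb libraries. Values after ± are SD for CPM and standard errors for log2 fold changes. The comparisons were each dose with dose 0 and the 2 doses with each other inside each batch, the difference of the responses between batches at each dose, and the untreated groups with each other. Where the lower group holds no read the fold is a lower bound against 3 counts over the group, and where it holds 1 to 3 counts it is a ratio of CPM with its 95% counting interval. Setting these genes to their bound left every affected list median as given.

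Camera (limma 3.58.1) tested 39 of 41 lists, those with at least 5 measured members, on log2 CPM (prior count 2) with a preset gene correlation of 0.01 and, as an alternative, with a correlation estimated for each list. All 980 list symbols were found in the table. Each list's count of changed genes is given with the adjustment over all tested genes and again adjusted over the list alone.

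The groups, comparisons, tests, alternatives and lists and the rule for naming genes were set before the data were examined. The rule names the 12 largest rises and 12 largest falls in each comparison with dose 0 among genes past the threshold with all 3 treated libraries beyond all 3 untreated ones, at least 5 CPM in the higher group and a gene symbol that is not a clone name. It also names up to 4 members of each list with the smallest p at dose 100 in each batch, 12 genes in every comparison (APP, TREM2, APOE, CD36, MSR1, IL1B, TNF, NLRP3, HMOX1, ABCA1, GPNMB and LPL) and the 8 largest response differences either way. A few genes this rule reaches are not reported here. CXCL8, RSAD2, CXCL10, TDO2, KYNU, KMO, TOP2A, IFI6, SLC7A11, TAP1, HK2, SORL1, MMP9, CCL5, CCL8 and RPL3 were chosen after their values were seen wherever this rule does not reach them, and so were the members named as exceptions to a list's direction and all genes named between doses 30 and 100 and between the untreated groups.

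Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit on 1 batch alone, replicate number as a block, leaving out each library, and the estimated list correlation. Replicate numbers were checked for pairing on the residuals of each group. In 30sAb vs 0sAb libraries of the same number correlated (r 0.65, 0.39 and 0.57, each best with its own number), so the blocked count stands beside the unblocked one there, and in the other 5 comparisons of doses the lowest r was -0.05, -0.05, 0.03, -0.02 and -0.03. Leaving out replicate 3 of 100sAb from the shared calls and the slope between batches was added after its values were seen, and so were the blocked counts of list members in 30sAb vs 0sAb.

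The fits were tested on simulated data with the depths of the 18 libraries, 16527 genes and 200 of them changed in 100Ab vs 0Ab. Each gene's simulated spread was the one estimated over all 18 libraries, the same in every group. The real sAb libraries spread more widely than the Ab ones, so the false calls below do not tell how many arise from that. At 1.5-fold edgeR recovered 23 of 100 and at 3-fold 95 of 100 with 2 false calls, and DESeq2 34 and 97 with 24 false calls. For the difference of responses at dose 100 edgeR recovered 4 and 81 with 2 false calls. Raising the 23 glycolysis genes 1.5-fold gave camera adjusted p = 1.41e-42 with the preset and 5.01e-07 with the estimated correlation. With the preset 0 other lists were called, and with the estimated correlation the others were not counted. The simulated genes were drawn independently of each other and no other list was moved. This check therefore cannot tell how either setting performs on correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.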

Results

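The macrophage-like cells of both untreated groups expressed the surface receptor genes expected of phagocytes and kept some proliferation genes. CD36, which encodes a scavenger receptor that binds amyloid, stood at 1690 ± 125 CPM (TMM-scaled counts relative to library size) in 0Ab and 1022 ± 205 CPM in 0sAb. TREM2, a lipid and amyloid receptor gene tied to Alzheimer's disease risk, stood at 650.0 ± 96.2 and 502 ± 23.4 CPM. TOP2A, a topoisomerase gene used in dividing cells, stood at 186 ± 8.84 and 312 ± 23.7 CPM. Group values here and below are means ± SD of 3 libraries. The cells were THP-1, a human monocytic leukaemia line, treated with PMA at 50 ng/ml for 48 h, kept without PMA for 5 h and then left with the peptide for 48 h. The 18 libraries form 6 groups of 3, labelled by peptide (Ab or sAb) and dose number (0, 30 or 100, with no unit given in the labels). All Ab libraries belong to 1 batch and all sAb libraries to another, so the 2 peptide labels cannot be told apart from the batches, while the doses are compared inside a batch. Libraries held 21532578 to 31666625 counted reads and 20540 to 23379 detected genes. Mitochondrially encoded genes took 0.475 to 1.494% of counts and the 10 most abundant genes 8.07 to 13.02%. Over 0Ab, 30Ab and 100Ab the mitochondrial share averaged 1.03, 0.51 and 0.72%, the top 10 share 10.4, 12.2 and 12.8% and the detected genes 22024, 20918 and 20980. Over 0sAb, 30sAb and 100sAb these were 1.313, 1.08 and 1.073%, 8.5, 8.4 and 9.8%, and 22893, 23099 and 22848. Of 58233 genes in the count table, 16527 were expressed enough to be tested, and they hold 99.93 to 99.96% of counts.

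Inflammatory genes rose steeply at dose 100 of the Ab peptide. IL1B, the interleukin-1 beta gene (ENSG00000125538, chromosome 2, 112829751 to 112836903, minus strand), rose from 82.8 ± 9.49 to 20440 ± 645 CPM (log2 7.95 ± 1.05, adjusted p = 9.93e-06). CXCL8, which encodes a neutrophil attractant (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand), rose from 20.3 ± 2.66 to 24960 ± 2530 CPM (log2 10.27 ± 1.12, adjusted p = 1.28e-06). TNF (ENSG00000232810, chromosome 6, 31575567 to 31578336, plus strand) rose from 1.90 ± 0.546 to 256 ± 22.4 CPM (log2 7.07 ± 1.24, adjusted p = 1.53e-04). The kynurenine pathway gene TDO2 rose from 146 ± 10.5 to 2134 ± 345 CPM (log2 3.87 ± 0.23, adjusted p = 1.95e-09). Several genes had no read in 0Ab, and against a floor of 3 counts in that group CSF3 was at least 2150-fold higher, IL6 at least 933-fold, CSF2 at least 862-fold and CLEC4E at least 462-fold. With 1 to 3 counts in 0Ab, IDO1 was higher 6980-fold (1250 to 276000), CCR7 4470-fold (1530 to 21700), CXCL13 3920-fold (1340 to 19000) and IL1A 1650-fold (564 to 8010), where the intervals cover counting error only. The other large rises were CXCL1 (log2 11.79 ± 1.49), CXCL2 (log2 10.31 ± 1.27) and SERPINB7 (log2 10.64 ± 0.65). Without replicate 1 of 0Ab the fitted log2 of SERPINB7, IDO1, CXCL13 and IL1A moved from 10.64, 12.29, 11.76 and 10.51 to 11.28, 14.09, 12.57 and 11.32, and without replicate 3 that of CCR7 from 11.94 to 12.76. In these genes, and in those named below as risen or fallen unless stated, the 3 libraries of 1 group lay beyond the 3 of the other. Counts of list members include genes whose libraries overlap. Of 31 NF-kB and inflammatory cytokine genes, 30 rose, among them CXCL5 (log2 9.80 ± 0.58), IRAK2 (log2 5.50 ± 0.54) and RELB (log2 2.90 ± 0.29). None fell, and TNFAIP2 did not pass (median log2 6.31; camera adjusted p = 7.04e-13, adjusted p = 0.426 with an estimated correlation). Among 27 immediate early and dissociation stress genes, 24 rose, such as FOSB (log2 6.56 ± 0.38), FOSL1 (log2 2.76 ± 0.19) and DUSP1 (log2 3.34 ± 0.32). KLF4 fell (log2 -4.33 ± 0.23, adjusted p = 7.99e-10), and IER2 and DUSP2 did not pass. Across the transcriptome 9407 genes changed in edgeR's quasi-likelihood test after Benjamini-Hochberg correction, 4643 higher and 4764 lower, 4855 of them at least 2-fold. Adjusted over the list alone, 31 and 25 members changed in these 2 lists.

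Interferon response genes and several antigen presentation genes also rose at dose 100 of Ab. IFI6, an interferon-induced mitochondrial protein gene, rose from 364 ± 30.9 to 3880 ± 703 CPM (log2 3.41 ± 0.31, adjusted p = 1.79e-07). CD74, the class II invariant chain gene, rose from 72.4 ± 2.01 to 302 ± 15.8 CPM (log2 2.06 ± 0.14, adjusted p = 6.52e-09). The class I gene HLA-B rose from 818 ± 23.0 to 2273 ± 143 CPM (log2 1.47 ± 0.14, adjusted p = 2.15e-07). Of 32 type I interferon response genes 28 rose and none fell, with IRF7 (log2 3.18 ± 0.30), OAS3 (log2 2.72 ± 0.27), HERC6 (log2 2.71 ± 0.32) and RSAD2 (log2 4.62 ± 0.61) as examples. IFIT2, USP18, CXCL10 and CXCL11 did not pass (CXCL10 from 0.430 ± 0.158 to 1.73 ± 0.272 CPM, adjusted p = 0.261). Fitted on the Ab batch alone CXCL10 was called higher (log2 1.98, adjusted p = 1.65e-04). Of 15 MHC class I antigen presentation genes 9 rose, including HLA-F (log2 3.41 ± 0.26) and NLRC5 (log2 1.58 ± 0.13), and ERAP1 fell. Of 14 MHC class II antigen presentation genes 7 rose, CD80 most of all (log2 6.14 ± 0.84, adjusted p = 1.44e-05), while HLA-DQB1, HLA-DMA (log2 -1.67 ± 0.19, adjusted p = 2.24e-06) and HLA-DMB fell (camera adjusted p = 0.14). HLA genes are alike in sequence, so reads of 1 may be counted in another. Complement genes split, 10 higher and 7 lower of 18 with CFD not passing, from C1S (log2 3.58 ± 0.25) and SERPING1 (log2 2.69 ± 0.24) to CFP (log2 -3.12 ± 0.28) and VSIG4 (log2 -2.58 ± 0.24). Inflammasome and pyroptosis genes split as well, 7 higher and 6 lower of 18, from IL1RN (log2 4.58 ± 0.33) and P2RX7 (log2 1.80 ± 0.18) to IL18BP (log2 -2.79 ± 0.12) and NLRC4 (log2 -1.40 ± 0.15). Among the risen was NLRP3 (log2 1.02 ± 0.27). The 5 lists had, in this order, 29, 10, 11, 17 and 13 members changed when adjusted over the list alone. The interferon list had camera adjusted p = 1.20e-09 (adjusted p = 0.455 with an estimated correlation) and the MHC class I list 0.00182 (adjusted p = 0.426 with an estimated correlation).

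Several amyloid receptor genes fell while several V-ATPase and matrix protease genes rose at dose 100 of Ab. CD36 (ENSG00000135218, chromosome 7, 80369575 to 80679277, plus strand) fell from 1690 ± 125 to 136 ± 10.2 CPM (log2 -3.64 ± 0.15, adjusted p = 4.09e-11). TREM2 (ENSG00000095970, chromosome 6, 41158506 to 41163186, minus strand) fell from 650.0 ± 96.2 to 106.1 ± 21.3 CPM (log2 -2.62 ± 0.16, adjusted p = 2.60e-09). The lipoprotein lipase gene LPL fell from 1919 ± 87.8 to 358 ± 43.0 CPM (log2 -2.42 ± 0.36, adjusted p = 3.53e-05). MMP9 (ENSG00000100985, chromosome 20, 46008908 to 46016561, plus strand), a gelatinase gene, rose from 952 ± 204 to 19950 ± 2150 CPM (log2 4.39 ± 0.28, adjusted p = 4.77e-09). Of 38 phagocytic and amyloid-binding receptors 20 fell, including TLR4 (log2 -4.53 ± 0.26), SCARB1 (log2 -3.19 ± 0.17) and MSR1 (log2 -1.48 ± 0.26), and 9 rose (camera adjusted p = 0.0507, adjusted p = 0.426 with an estimated correlation). Of 30 Alzheimer's disease risk locus genes 19 fell, such as SORL1 (log2 -4.42 ± 0.31), BIN1 (log2 -3.26 ± 0.16) and MS4A4A (log2 -3.42 ± 0.23). SPI1, ADAM17, CTSB, CTSH and RIN3 rose (camera adjusted p = 0.00182, adjusted p = 0.426 with an estimated correlation). APP, the amyloid precursor gene (ENSG00000142192, chromosome 21, 25880550 to 26171128, minus strand), stood at 553 ± 13.7 and 634 ± 16.9 CPM (log2 0.20 ± 0.07, adjusted p = 0.0251). This call ended when replicate 1 or 3 of 0Ab or of 100Ab was left out (log2 0.16, 0.21, 0.19 and 0.18). Amyloid precursor processing and amyloid-degrading genes gave 14 higher and 8 lower of 30, among them PLAU (log2 1.65 ± 0.10), MMP3 (log2 4.87 ± 0.41) and BACE1 (log2 -1.93 ± 0.17). Lipid-associated and disease-associated microglia-type genes gave 16 higher and 10 lower of 29, the fallen including FABP4 (log2 -3.93 ± 0.25), CD9 (log2 -2.21 ± 0.13), GPNMB (log2 -0.67 ± 0.11) and CLEC7A (log2 -1.85 ± 0.17). Lysosomal hydrolases and membrane proteins split into 17 higher and 18 lower of 47, from LGMN (log2 2.75 ± 0.15) and GLA (log2 1.86 ± 0.17) to LIPA (log2 -2.53 ± 0.13). Of 15 V-ATPase subunits 10 rose, such as ATP6V1A (log2 1.17 ± 0.07) and ATP6V1F (log2 1.36 ± 0.13), and ATP6V0A1 fell (camera adjusted p = 0.00182, adjusted p = 0.426 with an estimated correlation). Of 35 autophagy genes 23 rose, including SQSTM1 (log2 1.89 ± 0.16) and WIPI1 (log2 2.10 ± 0.18), and ULK2 and ATG10 fell. Of 32 endocytosis and macropinocytosis genes 10 fell, DNM1 (log2 -2.46 ± 0.16, adjusted p = 6.27e-09) among them, and DNM2, SNX9 (log2 3.11 ± 0.17, adjusted p = 8.76e-10), RAB5A, RAB7A and EHD1 rose. Of 18 matrix metalloproteinases and inhibitors 12 rose, such as MMP10 (log2 5.53 ± 0.48), MMP19 (log2 4.08 ± 0.33) and ADAMDEC1 (log2 3.77 ± 0.29), while MMP2, TIMP2, TIMP3 and ADAMTS1 fell. Counts adjusted over the list alone were 30, 25, 22, 27, 37, 13, 26, 13 and 16 in these 9 lists in this order.

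Redox, sugar and integrated stress response genes rose in large part at dose 100 of Ab, while LXR targets moved both ways. SLC7A11, the cystine importer gene (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand), rose from 12.9 ± 1.91 to 1834 ± 142 CPM (log2 7.15 ± 0.29, adjusted p = 4.81e-11). TXNRD1, a thioredoxin reductase gene, rose from 233 ± 12.4 to 1411 ± 31.4 CPM (log2 2.60 ± 0.10, adjusted p = 2.29e-11). The hexokinase gene HK2 rose from 49.4 ± 3.60 to 575 ± 18.3 CPM (log2 3.54 ± 0.11, adjusted p = 7.76e-12). VEGFA rose from 15.1 ± 1.13 to 602 ± 48.7 CPM (log2 5.32 ± 0.26, adjusted p = 2.57e-10). Of 26 NRF2 and oxidative stress genes 22 rose, including GCLM (log2 2.65 ± 0.14) and HMOX1 (log2 0.92 ± 0.22). AKR1B1 and CAT fell, and GSR and SOD1 did not pass (camera adjusted p = 5.30e-07, adjusted p = 0.265 with an estimated correlation). Of 23 glycolysis genes 19 rose, such as ALDOC (log2 2.80 ± 0.19) and SLC2A1 (log2 1.76 ± 0.12), HK3 fell (log2 -3.77 ± 0.18, adjusted p = 2.02e-10), and PFKL, PFKP and PGAM1 did not pass. Of 20 hypoxia response genes 18 rose, P4HA2 (log2 1.82 ± 0.11) and BNIP3L (log2 1.86 ± 0.12) among them, and EGLN1 and MXI1 fell. These 2 lists had the lowest camera adjusted p with an estimated correlation (0.125 for each). Of 27 ATF4 integrated stress response genes 19 rose, such as CEBPB (log2 3.68 ± 0.22), SESN2 (log2 2.41 ± 0.16) and SLC3A2 (log2 2.31 ± 0.10), and VLDLR, NUPR1 and STC2 fell. Of 29 cytosolic heat shock and proteasome genes 19 rose, including DNAJB4 (log2 1.57 ± 0.17), STIP1 (log2 0.87 ± 0.12) and PSMD11 (log2 0.78 ± 0.09). HSPB1 (log2 -1.33 ± 0.12, adjusted p = 2.54e-07) and CLU fell. The endoplasmic reticulum unfolded protein response list gave 7 higher, such as XBP1 (log2 1.25 ± 0.24) and DNAJC3 (log2 0.70 ± 0.11), and HSP90B1, PDIA6, CALR and CRELD2 lower of 24. Cholesterol biosynthesis genes gave 10 higher of 24, among them INSIG1 (log2 1.92 ± 0.21), SQLE (log2 1.74 ± 0.17) and MSMO1 (log2 1.24 ± 0.12), and 3 lower, MVK and TM7SF2 included (camera adjusted p = 0.334). Of 15 LXR targets and cholesterol efflux genes ABCA1 (log2 1.61 ± 0.27, adjusted p = 1.22e-04), NR1H2, PLTP, SMPDL3A and CD82 (log2 3.11 ± 0.22, adjusted p = 1.51e-08) rose. ABCG1, MYLIP, APOC1, LPCAT3 and SCD (log2 -0.84 ± 0.10, adjusted p = 4.88e-06) fell. APOE stood at 181 ± 12.8 and 174 ± 33.2 CPM (adjusted p = 0.796). Of 15 iron handling genes 7 rose, FTH1 (log2 2.23 ± 0.22, adjusted p = 4.20e-07), SLC11A1 (log2 2.55 ± 0.20, adjusted p = 3.07e-08) and TFRC (log2 0.85 ± 0.08, adjusted p = 3.12e-07) included. SLC40A1, STEAP3 and BDH2 (log2 -1.97 ± 0.21, adjusted p = 1.26e-06) fell. Of 5 metallothioneins 1, MT1F, rose (log2 1.09 ± 0.33, adjusted p = 0.0101). Fitted on the Ab batch alone MT1X (log2 0.669, adjusted p = 0.00608) and MT2A (log2 0.852, adjusted p = 2.03e-04) were called higher too. Adjusted over the list alone, 25, 20, 20, 23, 22, 11, 13, 10, 10 and 1 members changed in these 10 lists in this order.

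Cell division, ribosomal and progenitor genes fell at dose 100 of Ab. TOP2A (ENSG00000131747, chromosome 17, 40388516 to 40417950, minus strand) fell from 186 ± 8.84 to 39.1 ± 5.39 CPM (log2 -2.24 ± 0.16, adjusted p = 1.19e-08). The mitotic kinase gene PLK1 fell from 34.7 ± 1.70 to 5.70 ± 0.392 CPM (log2 -2.60 ± 0.18, adjusted p = 7.72e-09). RPL3, a large ribosomal subunit gene, fell from 1433 ± 160.0 to 701 ± 44.5 CPM (log2 -1.03 ± 0.11, adjusted p = 6.76e-07). The progenitor receptor gene FLT3 fell from 35.7 ± 4.82 to 1.67 ± 0.335 CPM (log2 -4.41 ± 0.20, adjusted p = 1.11e-10). All 31 of 31 G2 and M phase genes fell, TPX2 (log2 -1.97 ± 0.14) and BUB1B (log2 -2.10 ± 0.15) among them (median log2 -1.98; camera adjusted p = 7.04e-13, adjusted p = 0.426 with an estimated correlation). Of 30 S phase genes 27 fell, such as E2F1 (log2 -1.28 ± 0.12), CDT1 (log2 -1.65 ± 0.17) and MCM5 (log2 -0.96 ± 0.10), and RRM2, POLD3 and SLBP did not pass. Of 45 cytosolic ribosomal protein genes 39 fell and none rose (median log2 -0.60), including RPL22 (log2 -0.92 ± 0.09), RPL13 (log2 -0.87 ± 0.10) and RPS23 (log2 -0.99 ± 0.12). Nuclear oxidative phosphorylation genes gave 13 lower of 39, such as NDUFV1 (log2 -0.37 ± 0.08), and UQCRC1 higher (log2 0.91 ± 0.12, adjusted p = 7.31e-06). Of 13 mitochondrially encoded genes MT-ND2 rose (log2 0.83 ± 0.21, adjusted p = 0.00327). MT-CO3 fell (log2 -0.83 ± 0.11, adjusted p = 1.40e-05), while MT-CO1, called lower with 1 treated library inside the untreated range (log2 -0.57 ± 0.22), lost its call when replicate 1 or 3 of 0Ab or replicate 1 or 2 of 100Ab was left out (-0.42, -0.57, -0.54 and -0.44). Of 18 undifferentiated THP-1 and myeloid progenitor genes 13 fell, including KIT (log2 -5.46 ± 0.32) and HOXA9 (log2 -0.98 ± 0.11), and CEBPE rose. Macrophage differentiation genes induced in PMA-treated THP-1 cells split into 10 higher and 8 lower of 20. Alternative activation macrophage genes split into 9 and 10 of 23, with MRC1 (log2 -7.10 ± 0.41), FOLR2 (log2 -4.53 ± 0.29) and ALOX15 (log2 -5.35 ± 0.41) among the fallen. Of 24 p53 target and apoptosis genes 7 rose, such as MCL1 (log2 1.35 ± 0.15), and 8 fell, such as GADD45A (log2 -2.07 ± 0.15) and BCL2L11 (log2 -2.53 ± 0.23). Their median was 0.01 and their mean -0.21. Of 30 actin cytoskeleton and adhesion genes 11 rose, ANKRD1 (log2 8.51 ± 0.31) and TPM4 (log2 1.09 ± 0.08) included, and 11 fell, CNN2 (log2 -2.51 ± 0.12) and FLNA (log2 -2.43 ± 0.18) included. Their median was -0.11 and their mean 0.37. The largest falls were DUSP27, at least 214-fold lower with no read in 100Ab, BBOX1 651-fold (222 to 3160), PDK4 492-fold (136 to 4070), NTS 507-fold (90.6 to 20000), CCR2 351-fold (96.7 to 2900), and F13A1 229-fold (63.1 to 1900). ANGPT1 205-fold (56.5 to 1700) and COL11A1 163-fold (55.5 to 793) followed, then MAMDC2 (log2 -8.04 ± 0.51), P2RY12 (log2 -7.60 ± 0.79), GALNT16 (log2 -7.55 ± 0.63) and TMEM37 (log2 -7.43 ± 0.41). The fitted log2 moved from -8.04 to -8.96 for MAMDC2 and from -7.19 to -8.05 for COL11A1 without replicate 1 of 100Ab. It moved from -9.20 to -10.11 for BBOX1 and from -8.57 to -10.60 for NTS without replicate 2, and from -7.62 to -10.44 for F13A1 without replicate 3. The 10 lists had, in this order, 31, 27, 41, 9, 2, 14, 18, 20, 15 and 22 members changed when adjusted over the list alone.

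Markers of other cell types stayed low in both untreated and treated THP-1 cells, with a few exceptions. The granule gene GNLY rose from 21.6 ± 0.919 to 62.7 ± 8.88 CPM (log2 1.54 ± 0.28, adjusted p = 2.33e-04). FCRLA, a B cell gene, rose from 3.82 ± 1.02 to 14.3 ± 2.80 CPM (log2 1.90 ± 0.27, adjusted p = 2.11e-05). The collagen-binding gene DCN was higher 460.0-fold (127 to 3810) and COL3A1 lower 62.9-fold (21.2 to 307), each with 1 to 3 counts in its lower group. Of 7 fibroblast markers COL1A1, DCN, PDGFRA (log2 1.11 ± 0.21, adjusted p = 2.53e-04) and FAP (log2 2.33 ± 0.26, adjusted p = 1.39e-06) rose and COL3A1 fell. Of 4 T and NK cell markers GNLY and CD8A rose. The call of CD8A ended without replicate 1 (1.42) or 2 (1.17) of 0Ab or replicate 3 of 100Ab (1.40) and moved to 2.38 without replicate 3 of 0Ab, against log2 1.57 with all. Of 5 B cell markers FCRLA rose and CD79A fell (log2 -1.86 ± 0.45, adjusted p = 0.00216). Of 3 epithelial cell markers CDH1 was higher 34.6-fold (11.4 to 171), its fitted log2 moving from 4.92 to 5.73 without replicate 1 of 0Ab, and KRT8 fell (log2 -1.54 ± 0.45, adjusted p = 0.0113). These 3 had a median of -0.51 and a mean of 0.96. Of 5 neuronal and glial markers SNAP25 (log2 4.50 ± 0.48, adjusted p = 1.05e-06) and SLC17A7 (log2 1.39 ± 0.28, adjusted p = 5.57e-04) rose, and MAP2 fell (log2 -1.47 ± 0.32, adjusted p = 9.26e-04). SYN1 was called higher (log2 1.30 ± 0.50) only with all libraries, the call ending without any 1 of the 6 (log2 1.146 to 1.382). Counts adjusted over the list alone were 6, 3, 2, 2 and 4 in these 5 lists in this order. With the preset gene correlation camera called 17 of 39 lists in 100Ab vs 0Ab, 12 higher and 5 lower. With an estimated correlation camera called 0 (lowest adjusted p = 0.125, 4 lists at unadjusted p < 0.05).

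**Figure D1:**
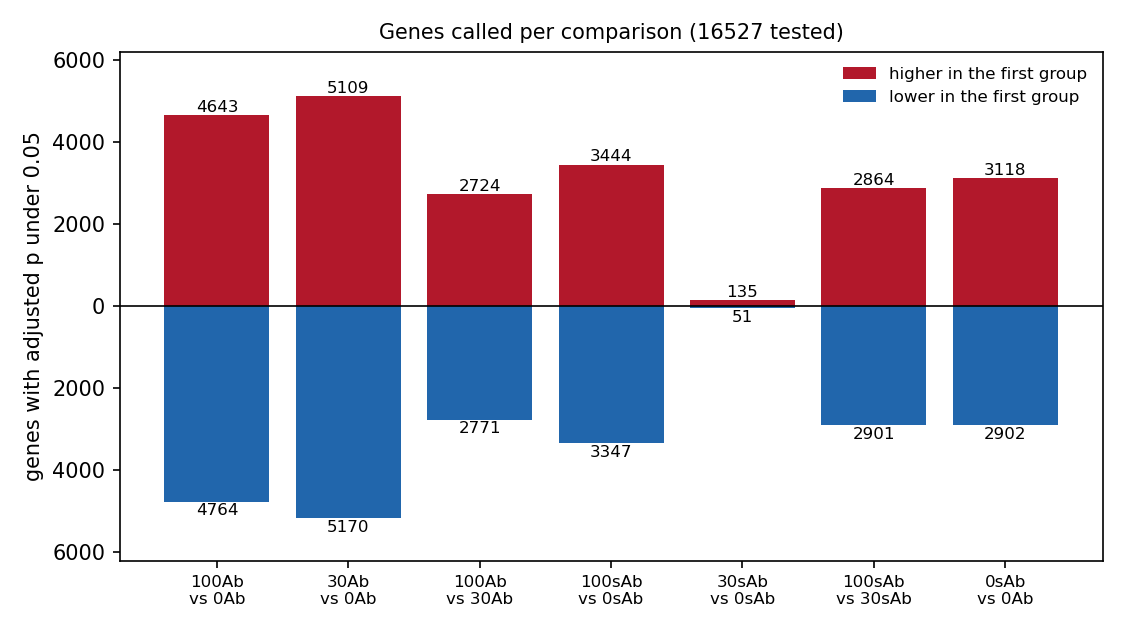
Number of genes higher and lower at adjusted p < 0.05 in each of 7 comparisons of 2 groups.

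Dose 30 of the Ab peptide raised interferon genes more than dose 100 did and lowered dividing-cell genes further. RSAD2, which encodes the antiviral enzyme viperin (ENSG00000134321, chromosome 2, 6865806 to 6898239, plus strand), rose from 4.47 ± 1.20 to 4610 ± 578 CPM (log2 10.01 ± 0.76, adjusted p = 1.84e-08). CXCL10, an interferon-induced chemokine gene (ENSG00000169245, chromosome 4, 76021117 to 76023497, minus strand), rose from 0.430 ± 0.158 to 455 ± 88.1 CPM (log2 10.04 ± 1.47, adjusted p = 2.13e-05), IFI6 rose to 8339 ± 153 CPM (log2 4.52 ± 0.33, adjusted p = 1.08e-08) and TOP2A fell from 186 ± 8.84 to 11.3 ± 1.32 CPM (log2 -4.04 ± 0.17, adjusted p = 9.82e-11). All 32 of 32 type I interferon response genes rose (median log2 5.57; adjusted p = 0.484 with an estimated correlation). The largest rises with reads missing from 0Ab were APOBEC3A, at least 2180-fold higher, CSF3 at least 374-fold, CLEC4E at least 257-fold, IL6 at least 240.0-fold and ZBP1 at least 157-fold. IDO1 was higher 26300-fold (4730 to 1040000), CXCL13 18500-fold (6330 to 89700) and CCR7 9850-fold (3370 to 47800), and TNFAIP6 (log2 10.95 ± 1.35), CCL8 (log2 10.39 ± 1.52) and IFI27 (log2 10.30 ± 1.02) also rose. Of 31 NF-kB and inflammatory cytokine genes 30 rose and none fell, IL1B (log2 5.28 ± 0.93), TNF (log2 5.58 ± 1.17), CXCL8 (log2 8.61 ± 1.05) and CCL5 (log2 5.82 ± 0.48) among them. MHC class I antigen presentation genes gave 14 higher of 15, with TAP1 (log2 3.77 ± 0.30) as an example, and ERAP1 lower, and immediate early and dissociation stress genes 23 higher of 27 and KLF4 lower. All 31 of 31 G2 and M phase genes fell (median log2 -3.41), 28 of 30 S phase genes fell with POLD3 rising, and 44 of 45 cytosolic ribosomal protein genes fell with RPS20 not passing. Of 29 lipid-associated and disease-associated microglia-type genes 18 rose, while TREM2 (log2 -2.01 ± 0.16, adjusted p = 2.27e-08), LPL (log2 -1.14 ± 0.35, adjusted p = 0.0098), CD9, FABP4 and PLIN2 fell. Single genes that rose included MMP9 (log2 4.14 ± 0.28), SLC7A11 (log2 6.12 ± 0.28), HK2 (log2 3.25 ± 0.11), HMOX1 (log2 1.61 ± 0.23) and ABCA1 (log2 1.39 ± 0.27). Tryptophan-degrading genes rose too, TDO2 (log2 5.14 ± 0.24), KYNU (log2 3.72 ± 0.41) and KMO (log2 3.48 ± 0.48). Among the fallen were CD36 (log2 -1.75 ± 0.14) and SORL1 (log2 -5.77 ± 0.33). NLRP3 was called higher (log2 0.77 ± 0.27, adjusted p = 0.0218), a call that ended without any 1 of the 0Ab libraries (log2 0.76 to 0.77) or replicate 2 of 30Ab (0.71). APP stood at 594 ± 15.9 CPM (adjusted p = 0.215), MSR1 at 1542 ± 132 (0.167), GPNMB at 1237 ± 53.5 (0.105) and APOE at 169 ± 25 (0.637), none of them passing. Fitted on the Ab batch alone MSR1 (log2 -0.41, adjusted p = 7.64e-04) and GPNMB (log2 -0.22, adjusted p = 0.0079) were called lower, and DESeq2 called APP higher (adjusted p = 0.0476). The largest falls were DUSP27, at least 181-fold lower, P2RY12 234-fold (80 to 1140), COL11A1 206-fold (56.9 to 1710), GPA33 167-fold (57.0 to 814) and F13A1 129-fold (43.9 to 627), then MAMDC2 (log2 -8.36 ± 0.55), CEACAM6 (log2 -7.44 ± 0.24), NLRP12 (log2 -6.95 ± 0.53) and FCGBP (log2 -6.94 ± 0.94). Without replicate 3 of 30Ab the fitted log2 of FCGBP moved to -7.65 and that of GPA33 from -7.27 to -8.09, and without replicate 2 that of P2RY12 moved from -7.76 to -8.61. That of COL11A1 moved from -7.50 to -10.54 and -6.91 without replicates 2 and 3 of 30Ab. Those of IDO1 and CXCL13 moved from 14.20 and 14 to 16.01 and 14.82 without replicate 1 of 0Ab, and that of CCR7 from 13.09 to 13.91 without replicate 3 of 0Ab. In edgeR's quasi-likelihood test 10279 genes changed after Benjamini-Hochberg correction, 5109 higher and 5170 lower, 5584 at least 2-fold. Adjusted over the list alone, 32, 30, 15, 24, 31, 30, 44 and 23 members changed in these 8 lists in this order. Camera with the preset correlation called 17 lists, 12 higher and 5 lower, and 0 with an estimated correlation (lowest adjusted p = 0.481, 4 lists at unadjusted p < 0.05).

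From dose 30 to dose 100 of Ab the interferon genes dropped back while glycolysis, redox and dividing-cell genes stood higher. RSAD2 fell from 4610 ± 578 to 110.3 ± 28.5 CPM (log2 -5.39 ± 0.62, adjusted p = 8.62e-06). CXCL10 fell from 455 ± 88.1 to 1.73 ± 0.272 CPM (log2 -8.04 ± 1.30, adjusted p = 2.04e-04). CCL8, another interferon-responsive chemokine gene, fell from 268 ± 53.8 to 2.99 ± 0.672 CPM (log2 -6.49 ± 1.18, adjusted p = 5.44e-04), while TOP2A was higher at dose 100 than at dose 30 (log2 1.79 ± 0.16, adjusted p = 7.65e-07). All 32 of 32 type I interferon response genes fell, IFI6 (log2 -1.10 ± 0.28) included (median log2 -2.94; camera adjusted p = 1.97e-16, adjusted p = 0.239 with an estimated correlation). MHC class I antigen presentation genes gave 14 lower of 15 with TAPBP not passing, TAP1 (log2 -1.97 ± 0.27) among them (adjusted p = 0.0826 with an estimated correlation). The NF-kB and inflammatory cytokine list moved both ways, with IL1A, IL1B, CXCL3, CXCL5 and PTGS2 higher, CCL2, CCL5, CCL7 and CCL8 lower and the other 22 of 31 not passing. IL1B stood at 20440 ± 645 CPM against 3217 ± 239 (log2 2.67 ± 0.83, adjusted p = 0.0203). This call ended when any 1 of the 30Ab libraries was left out (log2 2.61 to 2.71). The standard error of IL1B also carries the spread of the sAb libraries, where 100sAb ran from 931 to 10065 CPM. Neither TNF (log2 1.49 ± 0.94, adjusted p = 0.246) nor CXCL8 (log2 1.66 ± 0.77, adjusted p = 0.112) passed. Fitted on the Ab batch alone both did at about the same fold (TNF log2 1.469, adjusted p = 1.41e-06 and CXCL8 log2 1.638, adjusted p = 9.98e-07). Glycolysis genes gave 18 higher of 23 and PFKFB4 lower. The rise of HK2 (log2 0.29 ± 0.10, adjusted p = 0.0375) lost its call without replicate 1 (0.27) or 3 (0.28) of 30Ab or without a 100Ab library (0.28 and 0.32 without replicates 1 and 2). NRF2 and oxidative stress genes gave 19 higher of 26, with HMOX1, GCLC and FTL lower, and SLC7A11 (log2 1.03 ± 0.23) rose. G2 and M phase genes gave 28 higher of 31 with CCNB2, AURKA and KIF20B not passing. S phase genes gave 25 higher of 30 with POLD3 lower, and cytosolic ribosomal protein genes 30 higher of 45, RPL3 among them (log2 0.81 ± 0.11, adjusted p = 2.71e-05). Lysosomal hydrolases and membrane proteins gave 24 lower of 47 with GALC, PPT1 and, its libraries overlapping, MAN2B1 higher, and lipid-associated and disease-associated microglia-type genes 19 lower of 29 with CD9, CSF1 and HIF1A higher. CD36 fell further (log2 -1.90 ± 0.14, adjusted p = 1.04e-07), as did TREM2 (log2 -0.61 ± 0.15, adjusted p = 0.00578), and APOE stood at 174 ± 33.2 against 169 ± 25 CPM (adjusted p = 0.881). In edgeR's quasi-likelihood test 5495 genes changed after Benjamini-Hochberg correction, 2724 higher and 2771 lower at dose 100. The 10 lists had, in this order, 32, 14, 9, 20, 22, 28, 28, 35, 27 and 22 members changed when adjusted over the list alone. Camera with the preset correlation called 20 lists, 9 higher and 11 lower, and 0 with an estimated correlation (lowest adjusted p = 0.0826, 6 lists at unadjusted p < 0.05).

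**Figure D2:**
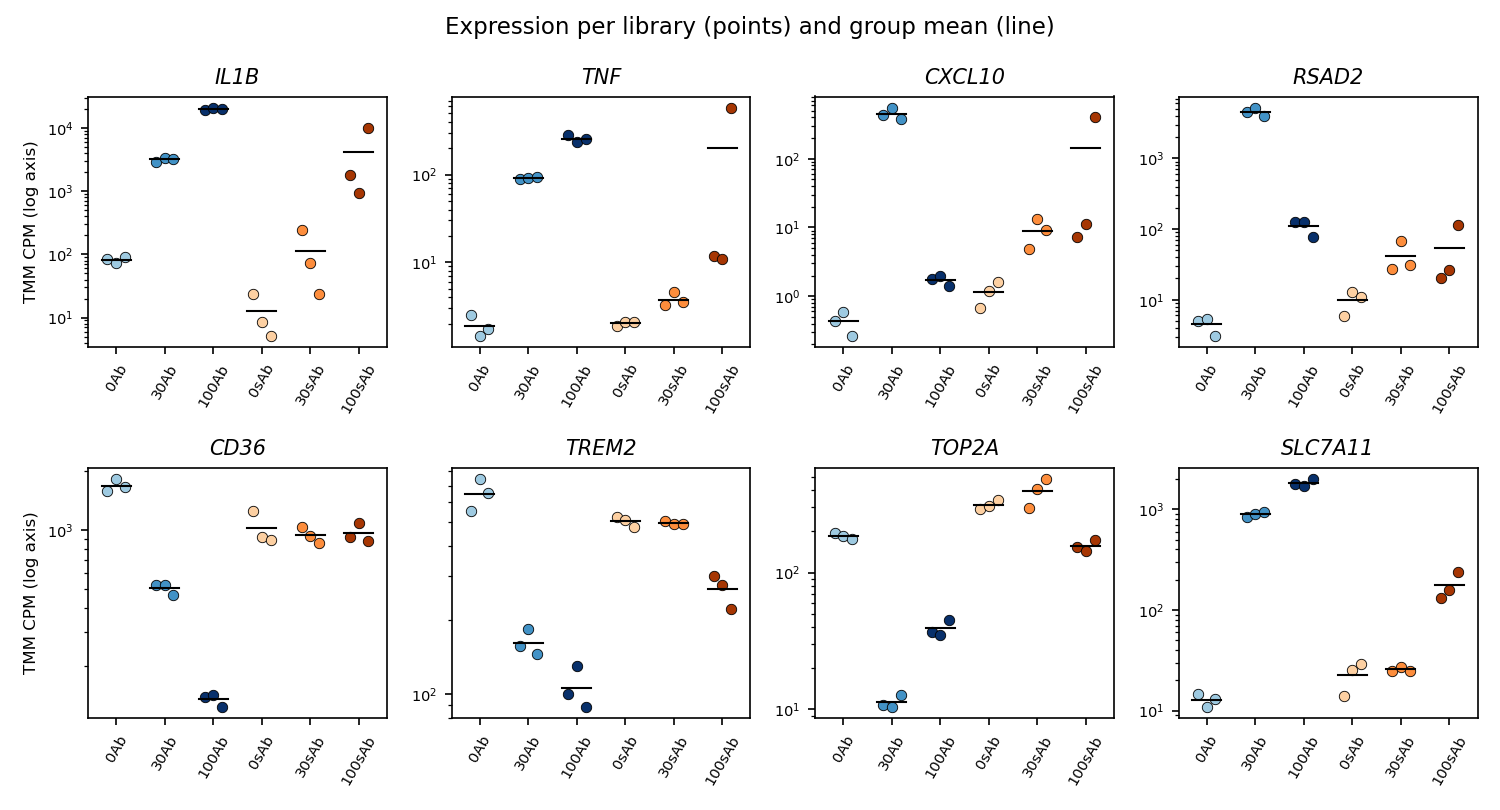
Expression of IL1B, TNF, CXCL10, RSAD2, CD36, TREM2, TOP2A and SLC7A11 in all 18 libraries on a log axis, in CPM. Points are libraries and lines are group means.

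At dose 100 the sAb peptide also raised cytokine and chemokine genes. CXCL8 rose from 3.27 ± 0.673 CPM to 1593, 1557 and 14680 in replicates 1, 2 and 3 (log2 10.83 ± 1.149, adjusted p = 3.16e-06). IL1B rose from 12.6 ± 10.0 CPM to 1804, 931 and 10060 (log2 8.41 ± 1.08, adjusted p = 1.88e-05; 9.26 without replicate 1 of 0sAb). CCL20, a lymphocyte and dendritic cell attractant gene, rose from 0.396 ± 0.320 CPM to 275.5, 163 and 1384 (log2 10.66 ± 1.27, adjusted p = 9.97e-06; 11.39 without replicate 1 of 0sAb). Without replicate 3 of 100sAb these 3 rose by log2 8.92, 6.77 and 9.19. CXCL13, a B cell attractant gene, rose from 0.0785 ± 0.136 to 156 ± 53.6 CPM (log2 10.76 ± 0.79, adjusted p = 1.16e-07; 10.14 and 15.05 without replicates 2 and 3 of 0sAb). Replicate 3 of 100sAb stood apart from replicates 1 and 2, with TNF at 576.9 against 11.9 and 10.77 CPM, so values without it are given for the genes named here that move by over 1.5-fold. TNF rose (log2 6.63 ± 1.21, adjusted p = 4.43e-04; 2.49 without replicate 3 of 100sAb), as did CCL4 (log2 10.44 ± 1.43, adjusted p = 3.53e-05; 6.55 without it) and CCL4L2 (log2 11.08 ± 1.75, adjusted p = 1.32e-04; 6.24 without it and 12.13 without replicate 3 of 0sAb). These 2 are near-identical copies whose reads may be shared. CXCL10 rose (log2 6.91 ± 1.26, adjusted p = 4.27e-04; 2.96 without replicate 3 of 100sAb). All 31 of 31 NF-kB and inflammatory cytokine genes rose, RELB (log2 3.37 ± 0.29), NFKB2 (log2 3.66 ± 0.37), IRAK2 (log2 5.56 ± 0.55) and CCL5 (log2 4.78 ± 0.46) among them (NFKB2 2.88, IRAK2 4.75 and CCL5 3.82 without replicate 3 of 100sAb). Their median log2 was 6.46 (or 30 genes and 3.82 without replicate 3; camera adjusted p = 2.48e-17, adjusted p = 0.282 with an estimated correlation). Of 32 type I interferon response genes 31 rose and STAT2 did not pass (median log2 2.03, or 23 genes and 1.14 without replicate 3). OAS3 (log2 1.96 ± 0.26) was steady and RSAD2 was not (log2 2.41 ± 0.55, adjusted p = 0.00239; 1.23 without). Immediate early and dissociation stress genes gave 22 higher of 27 and KLF4 lower. MHC class II antigen presentation genes gave 11 higher and none lower of 14, with HLA-DMA, HLA-DMB and CIITA not passing. With no read in 0sAb, CSF3 was at least 220.0-fold higher, SERPINB7 at least 191-fold, CSF2 at least 339-fold, CCL19 at least 202-fold and ACOD1 at least 376-fold, and IL12B was higher 1850-fold (331 to 73000). Without replicate 3 of 100sAb the calls of ACOD1 and IL12B ended (fitted log2 from 11.63 and 10.61 to 3.97 and 2.21; IL12B 12.33 without replicate 2 of 0sAb) and the fitted log2 of CSF3, SERPINB7, CSF2 and CCL19 moved from 10.80, 10.49, 11.48 and 10.73 to 8.19, 9.69, 6.80 and 5.09. The tryptophan-degrading genes IDO1 (log2 10.99 ± 1.60, adjusted p = 6.26e-05; 7.54 without replicate 3 of 100sAb), TDO2 (log2 4.23 ± 0.24, adjusted p = 1.16e-08) and KYNU (log2 3.05 ± 0.39, adjusted p = 2.04e-05; 2.09 without it) rose, as did KMO (log2 1.98 ± 0.46, adjusted p = 0.00268; 0.80 without replicate 3). In edgeR's quasi-likelihood test 6791 genes changed after Benjamini-Hochberg correction, 3444 higher and 3347 lower, 3097 at least 2-fold. Fitted on the sAb batch alone it called 4708. Counts adjusted over the list alone were 31, 31, 24 and 12 in these 4 lists in this order.

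Redox, sterol and matrix genes rose and progenitor genes fell at dose 100 of sAb. MMP9 rose from 275 ± 38.3 to 3132 ± 617 CPM (log2 3.51 ± 0.27, adjusted p = 1.81e-07). SLC7A11 rose from 22.8 ± 7.85 to 176 ± 55.3 CPM (log2 2.95 ± 0.24, adjusted p = 3.19e-07). FTH1, the ferritin heavy chain gene, rose from 2611 ± 278 to 12190 ± 2700 CPM (log2 2.22 ± 0.22, adjusted p = 1.57e-06). TREM2 fell from 502 ± 23.4 to 266 ± 41.2 CPM (log2 -0.92 ± 0.15, adjusted p = 1.89e-04). The mannose receptor gene MRC1 fell from 11.8 ± 2.42 to 0.847 ± 0.279 CPM (log2 -3.77 ± 0.32, adjusted p = 4.75e-07). APP rose from 507 ± 9.60 to 695 ± 18.4 CPM (log2 0.46 ± 0.07, adjusted p = 1.11e-04). Neither CD36, at 966 ± 111 CPM (adjusted p = 0.652), nor MSR1, at 628 ± 179 (0.929), NLRP3, at 132 ± 72.1 (0.536), APOE, at 170.3 ± 35.6 (0.0653), or ABCA1, at 126 ± 42.7 (0.288), passed, though APOE did without replicate 1 of 0sAb (-0.53) or replicate 3 of 100sAb (-0.56). Of 26 NRF2 and oxidative stress genes 19 rose, such as TXNRD1 (log2 1.55 ± 0.10), GCLM (log2 1.43 ± 0.14) and, with 1 treated library inside the untreated range, HMOX1 (log2 0.96 ± 0.22), and CAT and, with 1 treated library inside that range, GCLC fell. Of 24 cholesterol biosynthesis genes 17 rose, MSMO1 (log2 1.71 ± 0.12) among them, and PMVK and TM7SF2 fell. Glycolysis genes gave 16 higher of 23 with HK3 lower, hypoxia response genes 16 of 20, VEGFA (log2 2.93 ± 0.23) among them, with EGLN1 and MXI1 lower, and V-ATPase subunits 13 higher of 15 with ATP6V0A1 lower. Matrix metalloproteinases and inhibitors gave 12 higher of 18 with ADAMTS1 lower. Of 18 undifferentiated THP-1 and myeloid progenitor genes 13 fell, MYB the most (log2 -3.80 ± 0.46, adjusted p = 1.22e-05), and CEBPE rose. Falls came in 22 of 31 G2 and M phase genes, TOP2A included (log2 -0.99 ± 0.15, adjusted p = 1.01e-04), 17 of 30 S phase genes and 10 of 45 cytosolic ribosomal protein genes (21 without replicate 3 of 100sAb). Of 30 Alzheimer's disease risk locus genes 15 fell, BIN1 (log2 -2.36 ± 0.16) included, and 8 rose. Of 5 metallothioneins 3 were called lower, MT1E and, with overlapping libraries, MT1F and MT1G. The call of MT1F ended without replicate 2 or 3 of 0sAb or any 1 of 100sAb (log2 -0.57 to -0.97), and that of MT1G without replicate 2 or 3 of 0sAb or 1 or 2 of 100sAb (-1.88 to -2.27). Without replicate 3 of 100sAb 4 were called lower, with MT1E at -3.26 and MT1G at -3.92. Actin cytoskeleton and adhesion genes had a median of -0.02 and a mean of 0.86, with 10 higher and 9 lower of 30. The largest falls were F13A1 (log2 -5.87 ± 0.68), SERPINB2 (log2 -4.99 ± 0.76), ENHO (log2 -4.75 ± 0.40), DHRS9 (log2 -4.38 ± 0.35), MS4A3 (log2 -4.20 ± 0.85), TMEM37 (log2 -4.05 ± 0.30) and SELENOP (log2 -4.03 ± 0.40). MS4A3 moved to -5.31 without replicate 3 and SELENOP to -4.78 without replicate 1 of 100sAb. BBOX1 fell (log2 -3.91 ± 1.06, adjusted p = 0.0077; -1.60 and no call without replicate 1 of 0sAb), and LPL fell (log2 -1.38 ± 0.35, adjusted p = 0.00514; -0.70 without that library). Adjusted over the list alone, 21, 22, 19, 18, 14, 13, 14, 22, 19, 4, 24, 3 and 19 members changed in these 13 lists in this order. Camera with the preset correlation called 20 lists, 16 higher and 4 lower, and 0 with an estimated correlation (lowest adjusted p = 0.112, 4 lists at unadjusted p < 0.05).

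At dose 30 the sAb peptide moved few genes, some interferon genes and TDO2 among them. TDO2, a tryptophan dioxygenase gene, rose from 27.1 ± 5.29 to 171 ± 49.8 CPM (log2 2.66 ± 0.22, adjusted p = 3.83e-05). P3H2, a collagen hydroxylase gene, rose from 1.151 ± 0.130 to 22.4 ± 16.6 CPM (log2 4.28 ± 0.44, adjusted p = 2.22e-04; 3.56 without replicate 1 of 30sAb). IL4I1, an amino acid oxidase gene, rose from 40.0 ± 5.68 to 144 ± 61.1 CPM (log2 1.85 ± 0.27, adjusted p = 0.00285). The acid lipase gene LIPA fell from 1066 ± 37.3 to 561 ± 49.3 CPM (log2 -0.93 ± 0.12, adjusted p = 0.00144). CLEC5A (log2 2.28 ± 0.23, adjusted p = 2.20e-04) and the antiviral gene OAS3 (log2 1.98 ± 0.26, adjusted p = 0.0016) rose. FAM84B (log2 -1.18 ± 0.15, adjusted p = 0.00119), KLHDC8B (log2 -1.13 ± 0.16, adjusted p = 0.00285) and ATP1B1 (log2 -1.05 ± 0.15, adjusted p = 0.0034) fell. IL1B stood at 112 ± 114 against 12.6 ± 10.0 CPM (adjusted p = 0.0911), CXCL8 at 30.5 ± 33.7 against 3.27 ± 0.673 (0.0851) and RSAD2 at 42.2 ± 22.8 against 9.90 ± 3.56 (0.0804), none passing. With replicate number as a block IL1B (log2 3.109, adjusted p = 0.049) and RSAD2 (log2 2.148, adjusted p = 0.0146) were called higher, and by DESeq2 both were as well (adjusted p = 0.00958 and 0.0171). Without replicate 3 of 30sAb IL1B (3.64) and CXCL8 (3.70) passed, and without replicate 1 RSAD2 (2.32) and TOP2A (0.52). LPL did not pass (adjusted p = 0.534) but was called lower with the block (log2 -0.51, adjusted p = 0.0488). TREM2 (493 ± 6.95 CPM, adjusted p = 0.98), CD36 (941 ± 87.6, 0.821), TNF (3.76 ± 0.709, 0.839), APP (535 ± 22.7, 0.755) and TOP2A (398 ± 93.4, 0.362) did not pass either. GPNMB was called lower (log2 -0.62 ± 0.11, adjusted p = 0.0157), a call that ended without replicate 2 (-0.58) or 3 (-0.51) of 0sAb or replicate 2 of 30sAb (-0.63). In the type I interferon response list 8 of 32 genes rose and none fell (median log2 1.62; adjusted p = 0.485 with an estimated correlation). In the NF-kB and inflammatory cytokine list CCL5, NFKB2 and RELB rose and 28 of 31 did not pass. The call of CCL5 ended without any 1 of the 0sAb libraries or replicate 2 of 30sAb (log2 1.67 to 2.11, against 1.91). MMP9 and MMP12 rose among the 18 matrix metalloproteinases and inhibitors, and ASAH1 and LIPA fell among the 47 lysosomal hydrolases and membrane proteins. No member changed among 31 G2 and M phase, 30 S phase, 26 NRF2 and oxidative stress, 45 cytosolic ribosomal protein or 27 ATF4 integrated stress response genes in the fit without a replicate block. With the block 14 G2 and M phase genes and 10 S phase genes were called higher and none lower, 6 ribosomal and 2 NRF2 genes lower and none higher, and 23 interferon genes and 5 NF-kB genes higher. The 9 lists had, in this order, 27, 7, 3, 2, 10, 2, 0, 0 and 0 members changed when adjusted over the list alone. In edgeR's quasi-likelihood test 186 genes changed after Benjamini-Hochberg correction, 135 higher and 51 lower, with 1903 at unadjusted p < 0.05. DESeq2 called 508, and with replicate number as a block, which fits this comparison alone, edgeR called 1062. Fitted on the sAb batch alone edgeR called 1 gene, TDO2, and without replicate 2 or 3 of 0sAb or replicate 2 of 30sAb it called 50, 80 and 60. Camera with the preset correlation called 17 lists, 11 higher and 6 lower, and 0 with an estimated correlation (lowest adjusted p = 0.314, 2 lists at unadjusted p < 0.05).

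Between doses 30 and 100 of sAb the inflammatory genes rose and the dividing-cell genes fell. CXCL8 rose from 30.5 ± 33.7 to 5943 ± 7570 CPM (log2 7.61 ± 1.00, adjusted p = 4.63e-05; 5.70 without replicate 3 of 100sAb and 9.04 without replicate 1 of 30sAb). IL1B rose from 112 ± 114 to 4267 ± 5040 CPM (log2 5.25 ± 0.93, adjusted p = 4.97e-04; 3.61 and 6.47 without these). SLC7A11 rose from 25.7 ± 1.34 to 176 ± 55.3 CPM (log2 2.78 ± 0.24, adjusted p = 1.97e-06). TOP2A fell from 398 ± 93.4 to 157 ± 14.6 CPM (log2 -1.34 ± 0.15, adjusted p = 1.52e-05). TREM2 fell from 493 ± 6.95 to 266 ± 41.2 CPM (log2 -0.89 ± 0.15, adjusted p = 3.63e-04). MMP9 (log2 2.05 ± 0.26, adjusted p = 3.21e-05) and HK2 (log2 1.01 ± 0.10, adjusted p = 6.31e-06) rose. The size of the rise of TNF depends on replicate 3 of 100sAb (log2 5.72 ± 1.147, adjusted p = 0.00127; 1.58, adjusted p = 7.04e-06, without it). CD36 stood at 966 ± 111 against 941 ± 87.6 CPM (adjusted p = 0.859). All 31 of 31 NF-kB and inflammatory cytokine genes rose (28 without replicate 3 of 100sAb; adjusted p = 0.215 with an estimated correlation). Type I interferon response genes gave ISG20, IFIH1, CXCL10 and CXCL11 higher, each with overlapping libraries, and none lower of 32, but none higher and 7 lower without that library. S phase genes fell in 30 of 30 and G2 and M phase genes in 29 of 31, and NRF2 and oxidative stress genes gave 20 higher of 26 with CAT lower. In edgeR's quasi-likelihood test 5765 genes changed after Benjamini-Hochberg correction, 2864 higher and 2901 lower at dose 100. Counts adjusted over the list alone were 31, 0, 30, 30 and 21 in these 5 lists in this order. Camera with the preset correlation called 20 lists, 17 higher and 3 lower, and 0 with an estimated correlation (lowest adjusted p = 0.0825, 7 lists at unadjusted p < 0.05).

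**Figure D3:**
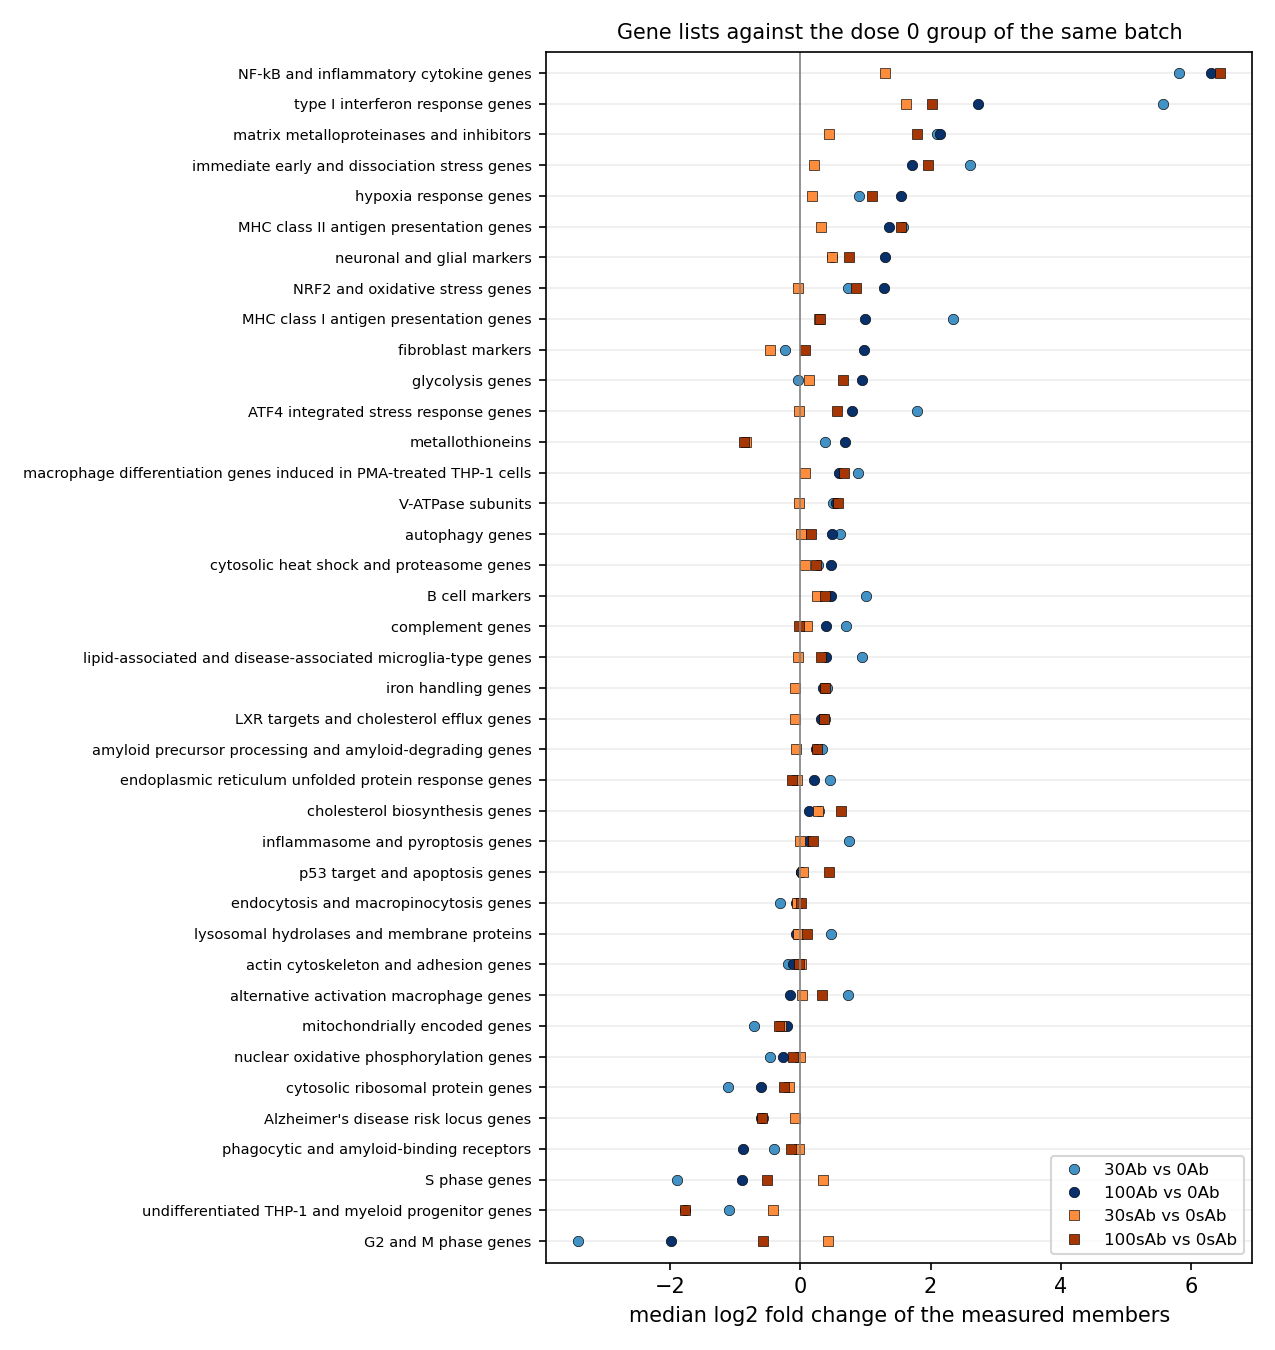
Median log2 fold change of 39 gene lists in the 4 comparisons with dose 0.

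The responses to dose 100 in the 2 batches, each with its own untreated group, shared many genes. IL1B, CXCL8, SLC7A11 and MMP9 rose in both, and TREM2, TOP2A, BIN1 and MRC1 fell in both. In 100sAb vs 0sAb and 100Ab vs 0Ab 2543 genes rose in both (968 expected by chance) and 2377 fell in both (965 expected), 4920 in the same direction, while 240 moved in opposite directions. Spearman's correlation of the log2 fold changes over all tested genes was 0.685, or 0.653 with 4462 genes in the same direction without replicate 3 of 100sAb. Between 30sAb vs 0sAb and 30Ab vs 0Ab 97 genes rose in both (42 expected), 38 fell in both (16 expected) and 26 moved in opposite directions (correlation 0.279).

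**Figure D4:**
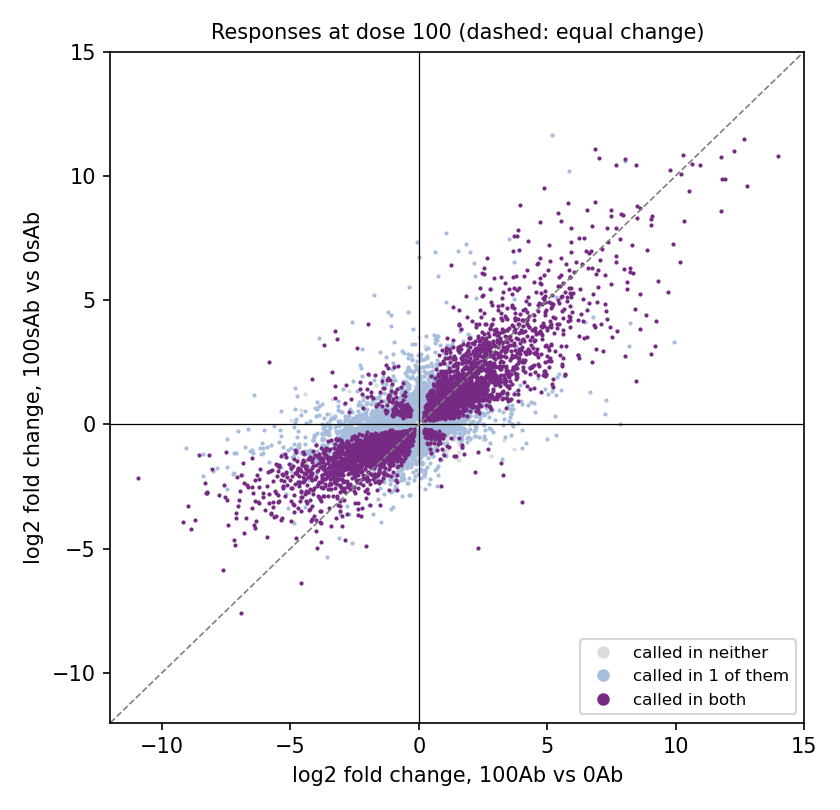
Log2 fold change of every tested gene in 100Ab vs 0Ab (horizontal) and 100sAb vs 0sAb (vertical), coloured by whether the gene was called in both, in 1 or in neither. The dashed line marks equal change.

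The untreated groups of the 2 batches differed in dividing-cell, sterol and protease genes, with no peptide in either. MMP9 was lower in 0sAb than in 0Ab (275 ± 38.3 against 952 ± 204 CPM, log2 -1.79 ± 0.25, adjusted p = 1.33e-04). So was TDO2 (27.1 ± 5.29 against 146 ± 10.5 CPM, log2 -2.43 ± 0.22, adjusted p = 4.56e-06). CD36 was lower as well (log2 -0.73 ± 0.13, adjusted p = 7.97e-04), while TREM2, at 502 ± 23.4 against 650.0 ± 96.2 CPM, did not pass (adjusted p = 0.0631; 0.0354 by DESeq2). IL1B and CXCL8 were called lower in 0sAb (log2 -2.72 ± 0.84, adjusted p = 0.0189 and log2 -2.64 ± 0.84, adjusted p = 0.0227). IL1B moved to -3.58 without replicate 1 of 0sAb. These calls ended for IL1B without replicate 2 (-2.51) or 3 (-2.35) of 0sAb and for CXCL8 without replicate 2 (-2.57) or 3 (-2.54) of 0sAb or replicate 3 of 0Ab (-2.52). Of 30 S phase genes 25 were higher in 0sAb and of 31 G2 and M phase genes 27, with none lower in either. Cholesterol biosynthesis genes were lower in 16 of 24, V-ATPase subunits in 11 of 15, cytosolic ribosomal protein genes in 23 of 45, and matrix metalloproteinases and inhibitors in 12 of 18 with ADAM8 and, its libraries overlapping, MMP25 higher. Undifferentiated THP-1 and myeloid progenitor genes were higher in 10 of 18, and macrophage differentiation genes induced in PMA-treated THP-1 cells lower in 11 of 20 with TGFBI higher. In edgeR's quasi-likelihood test 6020 genes differed after Benjamini-Hochberg correction, 3118 higher and 2902 lower in 0sAb. Adjusted over the list alone, 27, 30, 20, 11, 28, 14, 11 and 13 members differed in these 8 lists in this order. The labels give only a batch number beside the peptide label, and what else differed between the batches is not given in the sources used here.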

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

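The tests of the difference of responses were planned; of the explanations weighed below, the test on the untreated groups was chosen only after the result was seen. Each batch has its own untreated group, and each dose response was subtracted from that of the other batch in edgeR's quasi-likelihood test, so the items in this part are those whose response differed between the batches. Where a group holds 0 to 3 counts of a gene, the fitted difference depends on the prior count and is no bound.

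At dose 100 SLC7A11 rose in both batches but less with sAb (difference -4.20 on the log2 scale), while the G2 and M phase genes fell less with sAb. The difference passed for 3589 genes, 2044 with a higher and 1545 with a lower response to sAb. The higher ones were led by DUSP27 (8.74), MMP13 (8.33, or 9.82 and 7.71 without replicates 1 and 3 of 0sAb), NTS (7.35, or 9.38 without replicate 2 of 100Ab), OXTR (6.95, or 2.32 without replicate 3 of 100sAb, 7.54 without replicate 2 of it and 7.61 without replicate 1 of 0sAb), MAMDC2 (6.23, or 7.15 without replicate 1 of 100Ab), COL11A1 (6.05), PNOC (5.97, or 6.62 without replicate 1 of 0sAb) and TNFSF18 (5.88, or 4.99 without replicate 3 of 100sAb). The lower ones were led by SERPINB2 (-7.30), CACNA2D3 (-7.15), FRMPD2 (-6.71, or -8.53 without replicate 3 of 0Ab and -6.10 without replicate 3 of 0sAb), IL1R2 (-6.22), SFRP2 (-5.28, or -4.48 without replicate 1 of 0sAb), PCDH17 (-4.95, or -5.64 without replicate 3 of 100sAb), DCN (-4.77) and SLC7A11. The call of COL11A1 ended without any 1 of the 100Ab libraries, replicate 1 of 0Ab, replicate 2 or 3 of 0sAb or replicate 1 of 100sAb (5.10 to 6.90) and moved to 8.39 without replicate 1 of 0sAb. That of DCN ended without replicate 2 of 0Ab (-4.30) or replicate 2 or 3 of 0sAb (-4.48 each). Among the lists, 26 of 31 G2 and M phase genes had a higher response to sAb and 3 of 5 metallothioneins a lower one. No member of the 31 NF-kB and inflammatory cytokine genes passed with all libraries by edgeR, but 18 had a lower response to sAb without replicate 3 of 100sAb, and the interferon list went from 7 lower to 27 lower and 1 higher. Of 100 drawn splits 7 gave as many genes, the real one included (highest other 7441), so chance is not excluded by this count. All 6 others kept a real dose split in 1 batch, and the 84 draws without one gave at most 0 genes. Those 84 put the dose effect into the spread between replicates, so their 0 decides nothing.

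At dose 30 interferon, NF-kB, lysosomal and V-ATPase genes responded less to sAb than to Ab, and ribosomal and dividing-cell genes, which fell with Ab, had a higher response to sAb. The difference passed for 7529 genes, 3877 with a higher and 3652 with a lower response to sAb. The higher ones were led by DUSP27 (10.76), MAMDC2 (9.19), FCGBP (7.20), THBS2 (7.12), COL11A1 (7.06), P2RY12 (7.04), CEACAM6 (6.92) and BBOX1 (6.89). Without replicate 1 of 0sAb FCGBP, THBS2, COL11A1, P2RY12 and BBOX1 moved to 8.39, 8.17, 9.39, 7.99 and 9.22, and without replicate 1 of 30sAb FCGBP, THBS2, COL11A1 and BBOX1 to 6.23, 6.36, 5.28 and 5.73. COL11A1 moved to 10.10 and 6.47 without replicates 2 and 3 of 30Ab, P2RY12 to 7.89 without replicate 2 and FCGBP to 7.92 without replicate 3 of 30Ab. The lower ones were led by APOBEC3A (-10.85), CXCL13 (-10.08), TNIP3 (-9.66), TNFAIP6 (-8.46), RSAD2 (-7.92), ANKRD1 (-7.91), CXCL1 (-7.84) and IL1R2 (-7.80). The call of TNIP3 ended without any 1 of the 12 libraries, that of APOBEC3A without replicate 2 (-11.13) or 3 (-9.39) of 0sAb or replicate 1 (-10.65) or 3 (-10.76) of 30sAb, that of TNFAIP6 without replicate 2 (-8.37) or 3 (-8.21) of 0sAb, and those of CXCL13 (-5.78) and CXCL1 (-7.04) without replicate 3 of 0sAb. Without replicate 1 of 30sAb CXCL13, ANKRD1 and CXCL1 moved to -11.46, -8.70 and -8.43. ANKRD1 moved to -6.97 without replicate 1 of 0sAb and -7.25 without replicate 2 of 30sAb, and CXCL13 to -10.90 without replicate 1 of 0Ab and -10.68 without replicate 2 of 0sAb. Lower responses to sAb passed in 31 of 32 type I interferon response genes, 21 of 31 NF-kB and inflammatory cytokine genes, 24 of 47 lysosomal hydrolases and membrane proteins, 10 of 15 V-ATPase subunits, 21 of 35 autophagy genes, 17 of 27 ATF4 integrated stress response genes, 11 of 20 hypoxia response genes, 12 of 15 MHC class I antigen presentation genes and 19 of 27 immediate early and dissociation stress genes. Higher responses passed in all 31 G2 and M phase genes, 29 of 30 S phase genes and 42 of 45 cytosolic ribosomal protein genes. Of 100 drawn splits 9 gave as many genes, the real one included (highest other 8942), so chance is not excluded by this count. Of the 8 others 7 kept a real dose split in 1 batch and 1 was the real split of both batches with the sides exchanged in 1 of them. The 84 draws without a real dose split gave at most 0 genes. They too put the dose effect into the spread between replicates and decide nothing.

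The smaller response at dose 30 of sAb was weighed against 2 explanations. Wider replicate spread with equal effects would leave the fold changes alike, but over the 10279 genes called in 30Ab vs 0Ab the slope of the sAb on the Ab log2 fold change was 0.115 (0.094 to 0.131 with 1 library left out). At dose 100 that slope was 0.572 (0.49 without replicate 3 of 100sAb). The batch itself cannot be told apart from the peptide, since the untreated groups already differed in 6020 genes. A weaker peptide, a lower effective dose or cells in another state may each be the cause, and none of them was tested.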

How the results depend on the processing

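The shared calls without replicate 3 of 100sAb and the list members with a replicate block were chosen only after the result was seen. The gene counts were within 1.5 times of the first with RLE size factors, and with no filter, DESeq2, a fit on 1 batch and a replicate block apart from these exceptions. The 186 genes of 30sAb vs 0sAb became 286 with no filter on low counts, 508 with DESeq2, 1062 with a replicate block and 1 in a fit on the batch alone. The 5765 of 100sAb vs 30sAb became 3429 in a fit on the batch alone, and the 3589 with a different response at dose 100 became 5889 with a replicate block. With 1 library left out the counts ran from 8412 to 8665 in 100Ab vs 0Ab, 9386 to 9620 in 30Ab vs 0Ab, 4339 to 4624 in 100Ab vs 30Ab, 5561 to 6560 in 100sAb vs 0sAb, 50 to 379 in 30sAb vs 0sAb, 4244 to 6450 in 100sAb vs 30sAb, 2695 to 4422 and 6733 to 8046 for the response differences at doses 100 and 30, 4101 to 6313 in 0sAb vs 0Ab and 4289 to 4723 for shared calls. In 30sAb vs 0sAb the lowest were 50 without replicate 2 of 0sAb, 60 without replicate 2 of 30sAb and 80 without replicate 3 of 0sAb, and the highest 379 without replicate 1 of 30sAb. Lists called by camera were 17, 17, 20, 20, 17 and 20 in 100Ab vs 0Ab, 30Ab vs 0Ab, 100Ab vs 30Ab, 100sAb vs 0sAb, 30sAb vs 0sAb and 100sAb vs 30sAb, and 0 in each with an estimated correlation (4, 4, 6, 4, 2 and 7 at unadjusted p < 0.05). With 1 library left out they were 17 to 18, 15 to 19, 20 to 21, 19 to 23, 14 to 19 and 19 to 21.

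Of 5411 alternative values for 529 results of named genes, 5175 kept call and sign, 163 lost a call, 52 gained 1 and 21 turned in sign. Of 2106 for 234 list results 1823 kept call and sign of the median, 158 lost and 51 gained a call and 74 turned. Among the 1823, camera's direction alone turned in 42, none of them called, and these are not counted as turned. None of the results that turned was called with all libraries in the fit with group means (lowest adjusted p = 0.062), but with a replicate block LPL in 30sAb vs 0sAb and MBP in 100sAb vs 0sAb were called lower (adjusted p = 0.0488 and 0.0477). Apart from leaving out libraries, the median turned for actin cytoskeleton and adhesion in 100sAb vs 0sAb with RLE size factors (0.001), nuclear oxidative phosphorylation in 30sAb vs 0sAb with RLE size factors (0.004), and inflammasome and pyroptosis (-0.01) and autophagy (-0.009) in 30sAb vs 0sAb with a replicate block. The others turned with 1 library left out, and the values below are the lowest and highest log2 fold change or list median then. In 100Ab vs 0Ab these were APOE -0.22 to 0.053 and p53 target and apoptosis -0.007 to 0.032. In 100Ab vs 30Ab these were APOE -0.12 to 0.15, p53 target and apoptosis -0.044 to 0.006 and matrix metalloproteinases and inhibitors -0.063 to 0.022. In 100sAb vs 0sAb these were CD36 -0.19 to 0.086, CD79A -0.17 to 0.63, KRT8 -0.096 to 0.28, MBP -0.39 to 0.009, MSR1 -0.23 to 0.28, NLRP3 -0.30 to 0.50, inflammasome and pyroptosis -0.29 to 0.34, endocytosis and macropinocytosis -0.045 to 0.072, complement -0.37 to 0.17, alternative activation macrophage -0.12 to 0.52, actin cytoskeleton and adhesion -0.10 to 0.18, fibroblast markers -0.10 to 0.45 and B cell markers -0.038 to 0.63. In 100sAb vs 30sAb these were CD36 -0.065 to 0.10, type I interferon response -0.56 to 0.70, inflammasome and pyroptosis -0.24 to 0.40, endocytosis and macropinocytosis -0.007 to 0.052, LXR targets and cholesterol efflux -0.051 to 0.49, nuclear oxidative phosphorylation -0.24 to 0.001, mitochondrially encoded -0.23 to 0.15, cytosolic ribosomal protein -0.18 to 0.054, MHC class I antigen presentation -0.053 to 0.20, actin cytoskeleton and adhesion -0.016 to 0.19 and B cell markers -0.37 to 0.37. In 30Ab vs 0Ab these were APOE -0.21 to 0.001, glycolysis -0.13 to 0.043 and p53 target and apoptosis -0.061 to 0.099. In 30sAb vs 0sAb these were ABCA1 -0.42 to 0.22, CD36 -0.22 to 0.053, HMOX1 -0.048 to 0.34, LPL -0.97 to 0.06, MSR1 -0.36 to 0.20, inflammasome and pyroptosis -0.052 to 0.043, V-ATPase subunits -0.047 to 0.004, autophagy -0.036 to 0.044, phagocytic and amyloid-binding receptors -0.14 to 0.055, endocytosis and macropinocytosis -0.10 to 0.007, amyloid precursor processing and amyloid-degrading -0.13 to 0.013, LXR targets and cholesterol efflux -0.15 to 0.052, endoplasmic reticulum unfolded protein response -0.098 to 0.037, ATF4 integrated stress response -0.11 to 0.053, cytosolic heat shock and proteasome -0.004 to 0.22, nuclear oxidative phosphorylation -0.12 to 0.12, complement -0.15 to 0.16, alternative activation macrophage -0.063 to 0.12, macrophage differentiation -0.28 to 0.35, actin cytoskeleton and adhesion -0.058 to 0.079, Alzheimer's disease risk locus -0.16 to 0.011 and immediate early and dissociation stress -0.091 to 0.46.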

Other observations

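The tests on reads of a 30Ab or 100Ab library, on the NF-kB genes and on all genes for a scaling error, and the chemokine, kynurenine and interferon ligand families were chosen only after the result was seen. The splits of the libraries were planned.

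Most tested chemokine and tryptophan-degrading genes changed at dose 100 of either peptide and dose 30 of Ab. Of 32 tested chemokine genes 25 rose and 3 fell in 100Ab vs 0Ab, 28 rose and 3 fell in 30Ab vs 0Ab, 28 rose and 2 fell in 100sAb vs 0sAb, and 1 rose in 30sAb vs 0sAb. Most of the 28 stood at least 4-fold higher in replicate 3 of 100sAb than in 1 and 2 (CCL19 23.09, 0.17 and 0.13 CPM). CCL1 and CXCL9 libraries overlapped, CXCL9 at 1.151 ± 1.99 CPM in 100sAb against 0 ± 0 in 0sAb. In 100sAb vs 30sAb 27 were higher and 1 lower, and in 100Ab vs 30Ab 3 and 13. The 3 miss CXCL8, which the Ab batch alone called higher, as standard errors carry sAb spread. Of 8 tested kynurenine pathway genes TDO2, IDO1, KYNU, KMO and IDO2 rose in 100Ab vs 0Ab and QPRT and HAAO fell, while 5 rose and 3 fell in 30Ab vs 0Ab and 5 rose and 1 fell in 100sAb vs 0sAb. None of 22 interferon ligand genes had enough reads to be tested, with 0, 16, 11, 2, 2 and 7 counts in all over 0Ab, 30Ab, 100Ab, 0sAb, 30sAb and 100sAb, of which IFNB1 held 0, 15, 9, 2, 2 and 6. No bacterial product was measured, so endotoxin in the peptide stock was not tested.

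Replicate 3 of 100sAb stood apart from replicates 1 and 2 in inflammatory genes. It held 576.9 CPM of TNF against 11.9 and 10.77, 71.5 of IL12B against 0.0339 and 0.0956, and 409.8 of CXCL10 against 7.29 and 11.09. Reads of a 30Ab or 100Ab library in it would raise no gene above their highest, but 66.7% of the 183 genes it raised at least 4-fold, 122 genes, lay above the highest such library. For a mislabelled library of the other batch, the test with a bound set in advance did not decide. Over 57 genes that separate the batches replicate 3 had a median position of 0.264 on a scale from sAb (0) to Ab (1). This was just past the bound of 0.25. The other sAb libraries ran from -0.289 to 0.461 and the Ab libraries from 0.61 to 1.248. These libraries, unlike replicate 3, served to choose the genes. The place of replicate 3 among the sAb libraries and below every Ab library argues against a mislabelling but does not exclude it. A stronger response in that well or a different peptide preparation may be the cause and was not tested.

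Interferon response genes were lower at dose 100 than at dose 30 of Ab, RSAD2 and CXCL10 among them. On a scaling error between these libraries the 5 NF-kB genes called higher decide nothing, and the 2724 tested genes called higher follow from the centring by TMM. Such an error would move all genes alike and leave the gap between gene sets as it is. The median log2 was -2.94 over the interferon list and 0.011 over all tested genes. This gap argues against a scaling error as the source of the fall of the interferon list. The fall is thus relative to other genes, and absolute amounts were not measured. A single library was not the cause, as 32 interferon genes were still lower with any 1 of the 6 libraries left out. An earlier peak of the interferon response at dose 100, cell loss, or a limit set by other induced genes may be candidate explanations, and the single time point leaves them untested.

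With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave the most genes, 1 of 10, in 100Ab vs 0Ab (9407), 30Ab vs 0Ab (10279), 100Ab vs 30Ab (5495), 100sAb vs 0sAb (6791) and 0sAb vs 0Ab (6020), each with at most 0 in the others by edgeR, and in 100sAb vs 30sAb (5765, highest other 1927). In 30sAb vs 0sAb 3 of 10 gave as many as the real 186 (others 422 and 542). Those 2 splits part 1 of the 3 replicate pairs, and of the 4 splits parting all 3 pairs the real one gave 186 and the others at most 0. Splits with as many lists called by camera were 5, 3, 1, 1, 3 and 1 of 10 in 100Ab vs 0Ab (17, highest other 19), 30Ab vs 0Ab (17, 18), 100Ab vs 30Ab (20, 19), 100sAb vs 0sAb (20, 19), 30sAb vs 0sAb (17, 19) and 100sAb vs 30sAb (20, 19), so the list calls themselves carry no weight. Of 100 drawn splits 1, the real one, gave as many as 4920 genes changed in the same direction at dose 100 in both batches (highest other 0). No other split of a batch called a gene by edgeR in these 2 comparisons, so the others share 0 whatever the cause, and this count decides nothing about the sharing.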
